A study of Drosophila melanogaster with 9 samples.

How the data were processed

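Poly(A)-selected RNA of Drosophila melanogaster S2R+ cells, an embryonic cell line with haemocyte-like properties, was measured in 9 libraries. The labels name 3 groups of 3 libraries. The cells expressed a nuclear green fluorescent protein (GFP) as control, the wild-type Hox protein Ultrabithorax (Ubx-WT), or Ubx with the homeodomain change N51A (Ubx-N51A), all through the Gal4-UAS system. The labels' protocols speak of a myc tag on Ubx while the sample characteristics speak of GFP-tagged Ubx, and the tag was not settled here. Per the labels' protocols, 4 independent replicates were made per group, and 3 were kept after a principal component analysis. Such a selection can narrow the spread between libraries on which the p-values rest, and its effect was not measured here. The names of the deposited files carry a word about sorting that differs between the groups. If it refers to cells, sorting coincides with the groups and cannot be told apart from the proteins. The libraries were directional and were sequenced as 75 bp single-end reads.

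The deposited files hold raw read counts per FlyBase gene, 1 file per library, with 5 summary rows at the end of each. Per the submitters' processing notes, FastQC, Trimmomatic 0.36, STAR, HTSeq, DESeq and DESeq2 were used with the builds dm6 and BDGP6. Settings, the strand option of the counting and the annotation release are not given in the sources used here. Reads of a gene and of an antisense partner can therefore be mixed, and genes with near-identical copies, such as the Hsp70 genes, are uncertain where the counting could split their reads. Counts per gene hold no splice junctions, so splicing was not analysed here.

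Of 17559 genes per file, 17253 identifiers matched a symbol and 306 did not; the latter are given by identifier. Gene positions and exon lengths came from the Ensembl 115 annotation of BDGP6.54, the same assembly as dm6. Exon length means the summed length of all exons of a gene, with overlapping exons merged. Between 30967554 and 66828787 reads per library fell in genes. The summary rows stayed out of library sizes and tests. Reads outside genes made up 1.50% to 2.27% of the deposited counts, ambiguous reads 3.11% to 3.32% and reads with several alignments 3.26% to 5.05%. Genes of the mitochondrial genome held 1.92% to 5.87% of the reads in genes.

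The counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 9207, and libraries were scaled by the trimmed mean of M-values (TMM), with factors from 0.971 to 1.026. All 9 libraries entered one quasi-likelihood fit with the group as the only term (glmQLFit, glmQLFTest). The common biological coefficient of variation was 5.4%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries. At this depth the shallowest library, with 30967554 reads, resolves 1 CPM as about 31 reads. For genes with 1 to 3 reads in a whole group, the ratio of summed reads is given with an exact 95% binomial interval; with 0 reads it is a lower bound against a floor of 3 reads over the group. Such intervals cover counting error only.

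The code was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed. All 1.25-fold changes were simulated as rises, and all 2-fold and 4-fold changes as falls. Recovery of rises of 2-fold or more was therefore not tested. For Ubx-WT against GFP, edgeR recovered 64% of genes changed 1.25-fold, 78% of those changed 2-fold and 98% of those changed 4-fold, over 9090 genes, and 3.1% of its calls were false. For Ubx-N51A against GFP the shares were 66%, 76% and 90% over 9089 genes, with 7.3% false calls. For Ubx-N51A against Ubx-WT they were 66%, 82% and 94% over 9083 genes, with 5.4% false calls.

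Named genes follow a rule written before the data were examined. It takes Ubx, the Hox genes that pass the filter, and per comparison the 10 largest rises and 10 largest falls with a symbol among called genes. These genes must reach 2 CPM in the higher group with all libraries of one group above all of the other. The 2 largest rises and falls with only a number, and up to 2 called members per direction of each gene list, were added. Of the named genes called, 79 of 103, 51 of 79 and 44 of 65 kept their call without each library in turn, in the order of the comparisons above. The examples in the text were taken mostly from genes that kept their call, a choice made after the values were seen. Genes outside the rule are said to be so, or to be chosen after their values were seen. The genes exd, upd3, Hsp83 and DnaJ-1 also stand outside it.

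The 33 gene lists were also written before the data were examined; 33 list entries had no match in the files and 8 were matched through a synonym. The 31 lists with at least 5 measured members were tested on log2 CPM with camera (limma 3.58.1), with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. With an estimated correlation, none of the 12, 9 and 9 lists called in the 3 comparisons stayed called, and 3, 5 and 1 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes, called 13, 10 and 5 lists. Ubx was left out of its lists.

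Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, 2 other scalings, no filter and a stricter one, fits of 2 groups only, blocks by replicate number, stricter thresholds and leaving out each library. A fit without mitochondrial-genome genes and a fit corrected for exon length were added after the data were seen. The group comparisons share their GFP libraries, so 20 simulations of unchanged groups against those libraries were set beside the overlap of their calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.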

Results

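RNA from 9 libraries of S2R+ cells was compared in 3 groups of 3: cells with nuclear GFP, with wild-type Ultrabithorax (Ubx-WT) and with Ubx carrying the homeodomain change N51A (Ubx-N51A). Ubx is a Hox transcription factor that gives segments of the fly their identity, and the residue named in N51A lies in the part of the homeodomain that contacts DNA. The series title concerns binding of Ubx to RNA, splicing during transcription and RNA polymerase II, and the gene counts address which transcripts changed in amount. Reads in genes numbered 44547309, 39984588 and 51644437 in the GFP libraries, 41138781, 48902694 and 66828787 with Ubx-WT, and 30967554, 37236624 and 64221439 with Ubx-N51A. Genes of the mitochondrial genome took 1.92%, 3.06% and 3.43% of these reads with GFP, 2.77%, 4.91% and 3.34% with Ubx-WT, and 5.87%, 4.12% and 4.11% with Ubx-N51A. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 6.72, and their log2 CPM correlated at 0.9946 to 0.9979. The names of the deposited files carry a word about sorting that differs between the groups, and its meaning is not given in the sources used here. The first principal component held 48.1% of the variance and separated the Ubx-WT libraries from the rest, and the second held 19.3% and separated Ubx-N51A from GFP.

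Ubx itself was counted first, because it checks the labels. The GFP libraries held 14, 8 and 89 Ubx reads, the Ubx-WT libraries 71888, 69408 and 102681, and the Ubx-N51A libraries 51719, 76367 and 145254. Ubx (FBgn0003944; chromosome 3R, 16656623 to 16734426, minus strand, in BDGP6.54) reached 1530 ± 165 CPM with Ubx-WT and 2020 ± 279 CPM with Ubx-N51A, against 0.752 ± 0.853 CPM with GFP (mean ± SD, n = 3). The log2 fold change was 10.87 (SE 0.319; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.39e-10) for Ubx-WT and 11.26 (SE 0.321; adjusted p = 5e-10) for Ubx-N51A. Between the Ubx proteins it was 0.40 (SE 0.182; adjusted p = 0.287), which did not pass the test. The counts do not separate reads of the introduced gene from those of the cells' own.

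**Figure D1:**
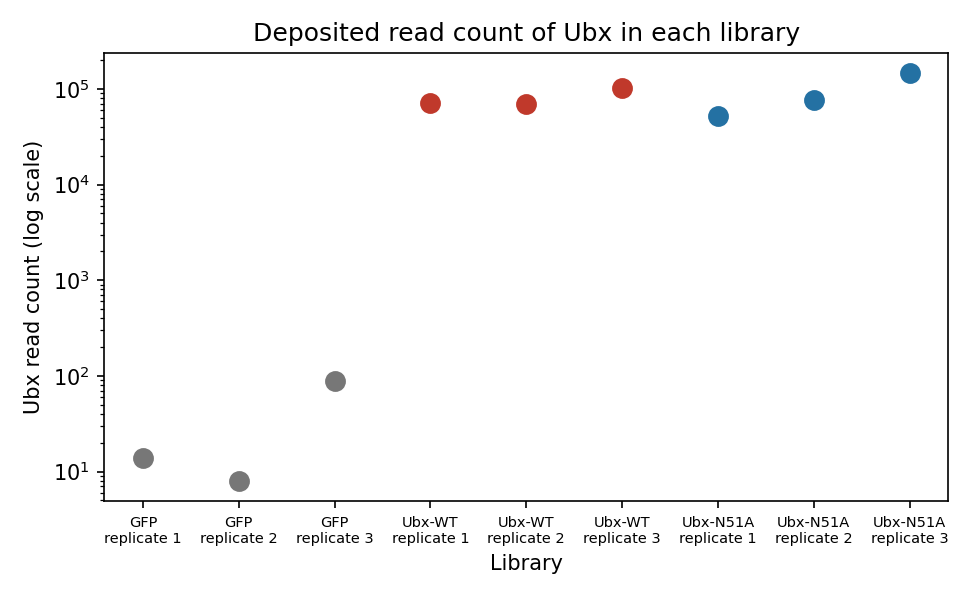
Raw Ubx reads per library on a log axis, with 3 libraries in each group. The GFP libraries held 8 to 89 reads, and every library of both Ubx groups held at least 51719.

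With Ubx-WT, genes that were almost silent in the GFP cells were transcribed. Osi6, a membrane protein of the Osiris family, had 3132 reads over the Ubx-WT libraries and 2 over the GFP libraries, a ratio of 1310 (95% interval 362 to 10800), and eg, a zinc finger transcription factor of the nuclear receptor type, had 1091 against 2, a ratio of 456 (126 to 3770). The bursicon receptor gene rk (2L, 13982743 to 14001248) rose from 0.0872 ± 0.0261 to 3.71 ± 0.278 CPM, a log2 fold change of 5.34 (SE 0.231; edgeR adjusted p = 9.21e-09). The zinc finger gene noc (2L, 14490859 to 14494019) rose by 4.77 (SE 0.161; edgeR adjusted p = 9.27e-10), and CBP, a calcium-binding protein (X, 7337352 to 7342731), by 4.53 (SE 0.204; edgeR adjusted p = 1.37e-08). At the other end, upd1, a ligand of the JAK-STAT pathway (X, 18305354 to 18309291), fell from 3.5 ± 1.14 to 0.186 ± 0.0736 CPM, a log2 fold change of -4.31 (SE 0.324; edgeR adjusted p = 1.57e-06).

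Other large rises in Ubx-WT cells included the calcium channel gene Ca-alpha1T (log2 fold change 4.55), the POU transcription factor pdm3 (3.90) and the T-box transcription factor bi (3.11). Of these bi stayed low, with 8 reads over the GFP libraries and 86 over the Ubx-WT libraries. GstS1, a glutathione S-transferase, rose from 5.35 to 26.8 CPM (log2 fold change 2.33, edgeR adjusted p = 9.27e-10). Gli, which encodes the septate junction protein Gliotactin, rose from 3.95, 4.69 and 4.54 CPM in the GFP libraries to a mean of 36.5 CPM. Among the falls, the cuticle protein gene Cpr49Ac changed by -4.14, the lipid phosphate phosphatase gene laza by -3.86 and the innexin gene Inx7 by -3.18. Of the Hox genes, Abd-B passed the expression filter beside Ubx. It had 53 reads with Ubx-WT and 1 with GFP, a ratio of 44.4 (95% interval 7.62 to 1780). Among the genes named as Hox cofactors and collaborators, exd, which encodes a homeodomain partner of Hox proteins, had 8141 to 11352 reads per GFP library and did not pass the test, and tio, which encodes a zinc finger protein, rose by 1.81. Of the textbook targets of Ubx 2 of 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.774). They include sca, which encodes a secreted fibrinogen-like protein (2.91), and the immunoglobulin-domain gene Ama (-1.48). With Ubx-N51A against GFP 0 of 7 targets rose and 1 fell (camera adjusted p = 0.149, fry adjusted p = 0.00667), which was Ama (-1.14). Between Ubx-N51A and Ubx-WT 1 of 7 was lower with Ubx-N51A (camera adjusted p = 0.146, fry adjusted p = 0.00735). Both counts were the same adjusted over the list alone.

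The genes of cell adhesion and guidance rose as a group with Ubx-WT: 11 of 28 measured members rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 5.26e-05, and adjusted p = 0.277 with an estimated correlation). The N-cadherin gene CadN rose by 2.87 (SE 0.224), and sli, which encodes the ligand of the Robo receptors (2R, 15869495 to 15922118), rose from 21.8 ± 0.65 to 88.6 ± 3.62 CPM, by 2.02 (SE 0.082; edgeR adjusted p = 4.95e-09). Nrt, which encodes neurotactin, fell by 0.50 on the log2 scale. In the Dpp pathway 6 of 20 genes rose and 2 fell, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.393 with an estimated correlation; 0.0513 in a fit corrected for exon length). Its BMP receptor gene wit rose by 1.80, while the glypican gene dally fell by 0.38. Single members of uncalled lists rose as well, such as the Wingless receptor gene fz2 (0.98) and the integrin gene if (0.54).

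Genes of the JAK-STAT and stress-induced list and of humoral immunity fell with Ubx-WT. In the former 6 of 11 genes fell and 1 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.277 with an estimated correlation). The ligand gene upd2 fell by 1.82, and Socs36E, which encodes an inhibitor induced by the pathway (2L, 18138675 to 18152417), fell from 146 ± 18.8 to 53.4 ± 0.89 CPM, a log2 fold change of -1.45 (SE 0.076; edgeR adjusted p = 5.92e-08). In the immunity list 6 of 23 fell and 1 rose, again with the same counts adjusted over the list alone (camera adjusted p = 0.00332, and adjusted p = 0.277 with an estimated correlation). The members that fell include PGRP-SC2, an amidase that cleaves peptidoglycan (-5.45), the antimicrobial peptide genes AttD (-2.09) and CecA1 (-1.83). PGRP-SC2 stood at 0.909 to 1.6 CPM with GFP and at 0.0146 to 0.0475 with Ubx-WT. The latter is at most a few reads per library, so the size of its fall is uncertain. The rise was in Dif, an NF-kappaB factor (0.24), and pirk, an inhibitor of the Imd pathway, fell by 1.49.

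Genes for making ribosomes were lower with Ubx-WT. In the nucleolus list 18 of 24 genes fell and none of the others rose, with 18 adjusted over the list alone (camera adjusted p = 7.58e-10, and adjusted p = 0.277 with an estimated correlation), among them nop5, a protein of small nucleolar RNPs (-0.42), and the fibrillarin gene Fib (-0.38). Of 81 ribosomal protein genes 14 fell, and 28 adjusted over the list alone, with a median log2 fold change of -0.16 (camera adjusted p = 1.75e-12, and adjusted p = 0.393 with an estimated correlation). Of 70 mitochondrial ribosomal protein genes 9 fell, and 4 adjusted over the list alone (camera adjusted p = 2.22e-07, and adjusted p = 0.571 with an estimated correlation). Of 67 oxidative phosphorylation genes 1 rose and 1 fell, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.00323, and adjusted p = 0.793 with an estimated correlation). That call ended without GFP replicate 1 (adjusted p = 0.0556) and without Ubx-WT replicate 2 (0.138). By fry neither the mitochondrial ribosomal list (fry adjusted p = 0.0827) nor the oxidative phosphorylation list (0.322) was called. These lists hold many short genes. Among genes of at least 5 CPM the median log2 fold change ran from -0.06 in the 10% with the shortest summed exon length to 0.03 in the 10% with the longest. In a fit corrected for exon length the lists stayed called lower. The nucleolus list kept 18 falls (camera adjusted p = 2.32e-10), and the ribosomal proteins had a median of -0.136 with 9 falls (2.32e-10). The mitochondrial ribosomal proteins had -0.084 with 7 falls (3.99e-05), and oxidative phosphorylation -0.047 with 1 rise and 1 fall (0.0397).

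Of the core spliceosome genes 2 of 35 fell with Ubx-WT, and 1 adjusted over the list alone (camera adjusted p = 0.000702, adjusted p = 0.579 with an estimated correlation, and fry adjusted p = 0.107). The clearest of them was Sf3b3, a part of the U2 snRNP (-0.27). The SR proteins and hnRNPs, which bind pre-mRNA and steer splicing, gave 3 rises and 3 falls in 25 genes, also adjusted over the list alone (camera adjusted p = 0.47). In the list of RNA polymerase II and elongation 2 of 32 fell, and 1 adjusted over the list alone (camera adjusted p = 0.155). Of the actin regulators 6 of 33 fell, such as the filamin gene cher (-0.35), with 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.00332, and adjusted p = 0.277 with an estimated correlation). In the heat shock list 5 of 18 fell and 1 rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0296, and adjusted p = 0.277 with an estimated correlation; 0.0585 without GFP replicate 3 and 0.0695 without Ubx-WT replicate 1). Its largest fall was in Hsp70Bb (-2.02), which held at least 98.2% of the reads of the 6 Hsp70 copies in every library. In the ER stress list 4 of 17 fell and 1 rose, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.393 with an estimated correlation; 0.0556 without GFP replicate 1, 0.0611 without GFP replicate 3 and 0.0646 without Ubx-WT replicate 1), including the chaperone genes Calr (-0.27) and Gp93 (-0.26).

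Across the genome edgeR called 1524 of 9207 genes between Ubx-WT and GFP, 803 higher and 721 lower, and 2822 had an unadjusted p under 0.05. The changes of at least 2-fold were mostly rises, 270 of 311. The libraries of the 2 groups did not overlap for 35.4% of all genes, where chance gives 10%. Without Ubx-WT replicate 3 the count was 990 and without GFP replicate 2 it was 1015.

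**Figure D2:**
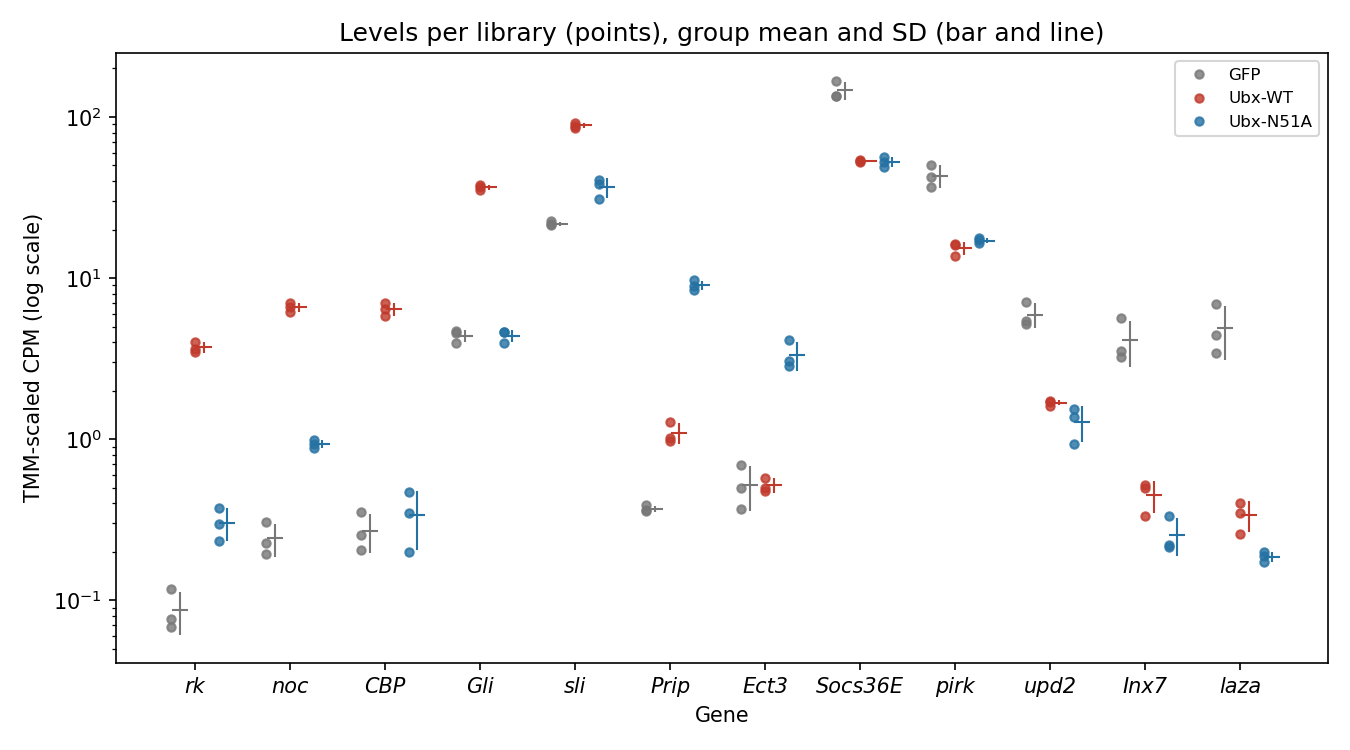
CPM per library on a log axis for 12 named genes in the 3 groups, with mean and SD. Points for rk, noc, CBP, Gli and sli lie highest with Ubx-WT, those for Prip and Ect3 with Ubx-N51A, and those for Socs36E, pirk, upd2, Inx7 and laza with GFP.

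With Ubx-N51A, the largest rise apart from Ubx was in Prip, an aquaporin gene (2R, 11436243 to 11442216), which rose from 0.37 ± 0.0176 CPM with GFP to 9.03 ± 0.603 CPM (n = 3), a log2 fold change of 4.60 (SE 0.146; edgeR adjusted p = 9.24e-10). The beta-galactosidase gene Ect3 (3R, 11999278 to 12003516) rose from 0.519 ± 0.16 to 3.33 ± 0.678 CPM, by 2.73 (SE 0.22; edgeR adjusted p = 7.9e-06). The FGF receptor gene htl rose by 2.76, CadN by 2.60, Kal1, an anosmin homologue, by 1.49, and the metalloprotease gene AdamTS-B by 1.27. Large falls were in Cpr49Ac (-5.29), upd1 (-4.91), PGRP-SC2 (-4.88), laza (-4.73) and Inx7 (-4.07), all of which had also fallen with Ubx-WT. Of these PGRP-SC2 stood at 0.0313 to 0.0538 CPM with Ubx-N51A, at most a few reads per library, so the size of its fall is uncertain. Ilp8, a relaxin-like peptide, fell by 3.40, and Mmp1, a matrix metalloprotease, by 0.76. Ilp8 was low in both groups, at 0.39 to 0.57 CPM with GFP and 0 to 0.067 with Ubx-N51A.

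Genes of the JAK-STAT and stress-induced list fell with Ubx-N51A in 6 of 11 cases, with 6 falls and 1 rise adjusted over the list alone (camera adjusted p = 3.27e-05, and adjusted p = 0.233 with an estimated correlation). Socs36E changed by -1.47 (SE 0.077; edgeR adjusted p = 3.18e-07), upd2 by -2.16 and the receptor gene dome by -0.40. In the immunity list 5 of 23 fell, with 6 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.273 with an estimated correlation; 0.0612 without GFP replicate 3 and 0.0779 without Ubx-N51A replicate 3), and pirk changed by -1.34. In the nucleolus list 14 of 24 fell, and 18 adjusted over the list alone (camera adjusted p = 1.25e-09, and adjusted p = 0.233 with an estimated correlation), with nop5 at -0.35 and Fib at -0.33. Heat shock genes fell in 4 of 18 cases, and in 7 adjusted over the list alone (camera adjusted p = 0.000449, and adjusted p = 0.233 with an estimated correlation). Among the integrins, laminins and basement membrane genes 4 of 20 fell, with 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.35 with an estimated correlation; 0.0506 without Ubx-N51A replicate 1), including Tig, the integrin ligand tiggrin (-0.82).

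The JNK and apoptosis list had 4 falls and 1 rise in 21 genes with Ubx-N51A, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.233 with an estimated correlation; 0.0612 without GFP replicate 3). Actin regulators fell in 3 of 33 cases, and in 7 adjusted over the list alone (camera adjusted p = 0.00878, and adjusted p = 0.273 with an estimated correlation). The ER stress list had 3 falls and 1 rise in 17 genes, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.035, and adjusted p = 0.35 with an estimated correlation; lost without any of 4 libraries, at most at 0.0777, and at 0.0544 corrected for exon length). The cell cycle list was called higher with 1 of 40 genes rising, also adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.927 with an estimated correlation; 0.365 without GFP replicate 3 and 0.302 without Ubx-N51A replicate 1). By fry the cell cycle list was not called (fry adjusted p = 0.351). Ribosomal protein genes did not pass (1 rise in 81, also adjusted over the list alone, and camera adjusted p = 0.922). In the fit corrected for exon length their median turned from 0.008 to -0.048 and the list was called lower (camera adjusted p = 0.0479). The SR proteins and hnRNPs gave 3 rises and 3 falls in 25, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.922), and mbl, which encodes the splicing regulator muscleblind, rose by 0.30. In the core spliceosome 1 of 35 fell, also adjusted over the list alone (camera adjusted p = 0.443), and in the RNA polymerase II list 0 of 32 were called, also adjusted over the list alone (camera adjusted p = 0.554).

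Between Ubx-N51A and GFP edgeR called 745 genes, 311 higher and 434 lower, and 2157 had an unadjusted p under 0.05. Changes of at least 2-fold numbered 94, of which 47 were rises. The groups did not overlap for 29.4% of all genes, where chance gives 10%. The count was 362 without GFP replicate 2, 398 without Ubx-N51A replicate 2, 440 without GFP replicate 1 and 490 without GFP replicate 3.

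The direct comparison of the Ubx proteins asks which transcripts differed between Ubx-WT and Ubx-N51A cells. The word about sorting in the file names also differs between these groups, and protein amounts were not measured here. A difference can therefore not be assigned to the residue changed in N51A alone. Gli (2L, 15756002 to 15762758) stood at 36.5 ± 1.16 CPM with Ubx-WT and 4.39 ± 0.37 CPM with Ubx-N51A (n = 3), a log2 fold change of -3.04 (SE 0.075; edgeR adjusted p = 6.61e-11), and in Ubx-N51A cells it differed from GFP by 0.01 (edgeR adjusted p = 0.959). Osi6 had 3 reads with Ubx-N51A against 3132 with Ubx-WT, a ratio of 851 (95% interval 291 to 4130), and eg had 2 against 1091, a ratio of 445 (123 to 3680). Lower with Ubx-N51A were also rk (-3.66), CBP (-4.11), Ca-alpha1T (-5.21), sca (-3.86), GstS1 (-1.98; edgeR adjusted p = 4.42e-09) and sli (-1.26; edgeR adjusted p = 5.21e-07). Higher with Ubx-N51A were Prip (3.07, SE 0.118; edgeR adjusted p = 4.42e-09), Ect3 (2.71), the C-type lectin gene rgn (1.32) and AdamTS-B (1.08). The eye pigment transporter gene w was higher by 0.62.

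**Figure D3:**
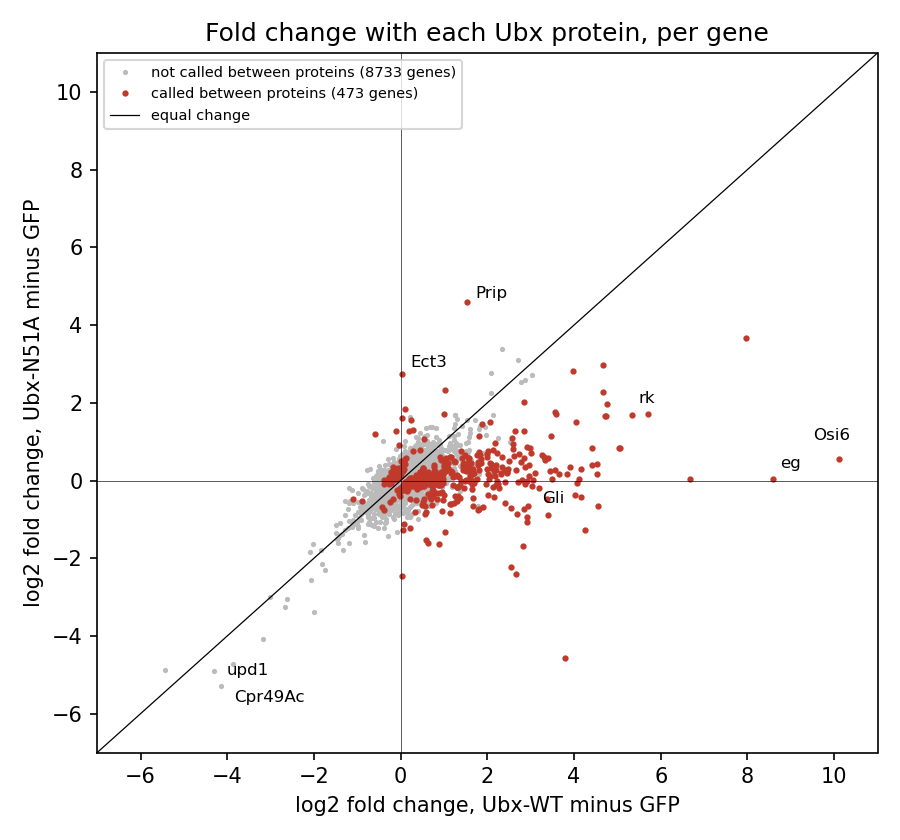
Log2 fold change against GFP with Ubx-WT (horizontal) and Ubx-N51A (vertical), 1 point per gene, with the 473 genes called between the proteins in red. Osi6, eg, rk and Gli lie far to the right, Prip and Ect3 at the top, and upd1 and Cpr49Ac at the lower left.

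Adhesion genes were lower with Ubx-N51A than with Ubx-WT: 5 of 28 fell, and 10 adjusted over the list alone (camera adjusted p = 0.000474, and adjusted p = 0.431 with an estimated correlation). In the fit corrected for exon length the adhesion list's median went from -0.147 to -0.104, with a weaker call (camera adjusted p = 0.0395). In the integrin and basement membrane list 4 of 20 fell, also adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.431 with an estimated correlation; 0.2 without Ubx-N51A replicate 1 and 0.247 in the fit corrected for exon length), including Tig (-1.15) and the nidogen gene Ndg (-1.14). In the Dpp list 4 of 20 fell and 1 rose, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.00506, and adjusted p = 0.431 with an estimated correlation; 0.0711 corrected for exon length). Of the epithelium, cuticle and fat body markers 1 of 12 fell, also adjusted over the list alone (camera adjusted p = 0.0388, and adjusted p = 0.431 with an estimated correlation; 0.0532 without Ubx-WT replicate 1, 0.0546 without Ubx-WT replicate 3 and 0.247 corrected for exon length). That gene was Fbp1, with 2 reads against 54.

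Genes for ribosomal proteins were higher with Ubx-N51A than with Ubx-WT, 14 of 81, and 37 adjusted over the list alone (median log2 fold change 0.16; camera adjusted p = 4.05e-19, and adjusted p = 0.431 with an estimated correlation), such as RpLP2 (0.53) and RpL36 (0.42). So were 5 of 70 mitochondrial ribosomal protein genes, and 16 adjusted over the list alone (camera adjusted p = 1.93e-14, and adjusted p = 0.431 with an estimated correlation). In oxidative phosphorylation 5 of 67 rose and 1 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 1.96e-07, and adjusted p = 0.57 with an estimated correlation). By fry the ribosomal, mitochondrial ribosomal and oxidative phosphorylation lists were not called (fry adjusted p = 0.0518, 0.0648 and 0.187). In the fit corrected for exon length the median of the ribosomal proteins was 0.075 with 4 rises, that of the mitochondrial ribosomal proteins went from 0.123 to 0.043 with 1 rise, and that of oxidative phosphorylation from 0.105 to 0.034 with 2 rises and 1 fall. In the core spliceosome 3 of 35 rose (1 in that fit), and 4 adjusted over the list alone (camera adjusted p = 0.00506, and adjusted p = 0.603 with an estimated correlation; 0.178 without Ubx-WT replicate 2), including SmB, a protein of the snRNP core (0.31). The cell cycle list was called higher with 0 of 40 members called, also adjusted over the list alone (camera adjusted p = 0.0297, and adjusted p = 0.647 with an estimated correlation; 0.0503 without Ubx-WT replicate 2, 0.181 without Ubx-WT replicate 3 and 0.313 without Ubx-N51A replicate 1). By fry the spliceosome and cell cycle lists were not called (fry adjusted p = 0.292 and 0.385). Genes matched to the ribosomal proteins in exon length and abundance had a median of 0.125. The SR protein and hnRNP list had 0 of 25 members called, also adjusted over the list alone (camera adjusted p = 0.346, and 0.0207, higher, in the fit corrected for exon length), and the RNA polymerase II list 1 rise in 32, also adjusted over the list alone (camera adjusted p = 0.346).

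Between the proteins edgeR called 473 genes, 113 higher and 360 lower with Ubx-N51A, and 1566 had an unadjusted p under 0.05. Of the 208 that differed at least 2-fold, 198 were lower with Ubx-N51A. The groups did not overlap for 22.8% of all genes, where chance gives 10%. The count was 124 with genes of at least 5 CPM and 302 without Ubx-WT replicate 3. In the fit corrected for exon length 12.8% of the calls were higher, against 23.9% here. Genes higher with Ubx-N51A numbered from 48, without Ubx-N51A replicate 2, to 126, without Ubx-WT replicate 1, over the fits without 1 library.

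**Figure D4:**
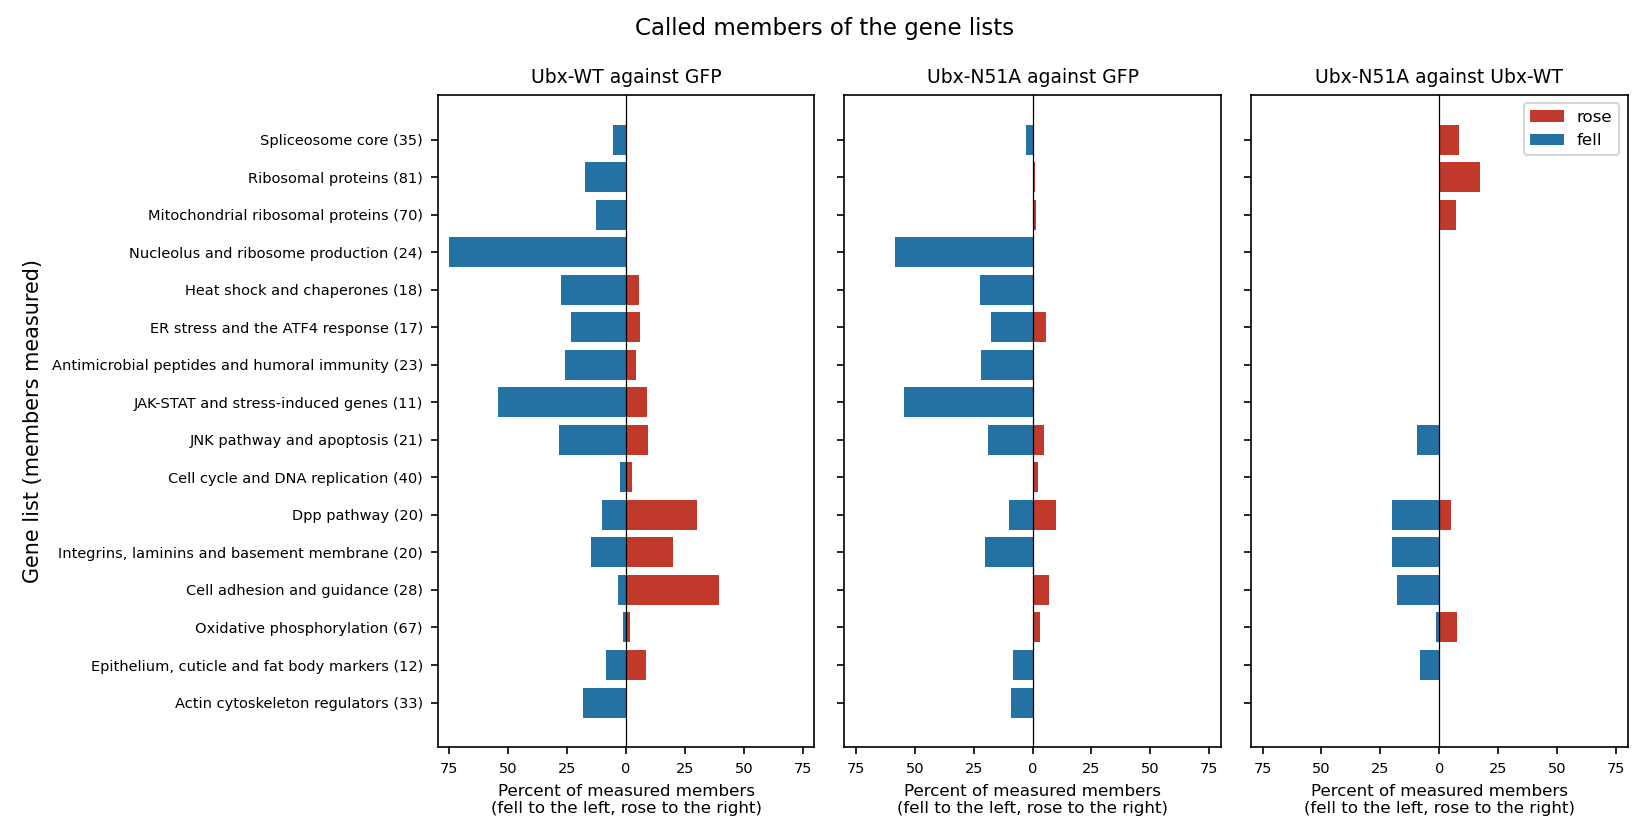
Percent of the measured members of 16 gene lists that fell or rose (edgeR adjusted p under 0.05), with a panel for each comparison. The nucleolus list shows 18 of 24 falls with Ubx-WT and 14 with Ubx-N51A, and the ribosomal proteins show 14 of 81 falls with Ubx-WT against GFP and 14 rises with Ubx-N51A against Ubx-WT.

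The responses to both proteins overlapped, more among falls than among rises. Of 9206 genes without Ubx, 350 were lower with both proteins and 193 were higher with both, where independent lists would share 34.0 and 27.0. Genes lower with both include upd1, Socs36E, pirk, PGRP-SC2, laza and Inx7, and genes higher with both include CadN, sli, htl and fz2. The called genes higher with Ubx-WT had a median log2 fold change of 0.53 with that protein and 0.18 with Ubx-N51A, and those lower had -0.21 and -0.17. Genes chosen by their call with Ubx-WT favour that protein, and the 310 called higher with Ubx-N51A had medians of 0.273 with Ubx-WT and 0.305 with Ubx-N51A, with 39 of the 73 that differed stronger with Ubx-N51A. Among the changes of at least 2-fold with Ubx-WT, 198 of 269 rises (73.6%) differed from Ubx-N51A in the direct test, against 1 of 41 falls (2.4%; two-sided Fisher's exact test, p = 1.94e-19, across genes, which are not independent). Over all genes called with Ubx-WT it was 320 of 802 rises (39.9%) against 29 of 721 falls (4%), and among genes chosen by a change of at least 2-fold with Ubx-N51A it was 21 of 46 rises against 6 of 47 falls. The comparisons share the GFP libraries, and in 20 simulations without any effect no gene was called in both by edgeR, against 543 here, but adjusted calls in unchanged groups are near 0 whatever the controls share. The fold changes correlated across genes at 0.503, and at 0.507 in the simulations, and their covariance was 0.0835 against 0.0125, a difference of 0.0711. With 3 controls no split leaves 2 on each side, so part of the excess in shared calls may come from the shared controls. The number of genes called in both was 281 without GFP replicate 2, 318 without Ubx-N51A replicate 2 and 329 without GFP replicate 1.

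Opposite calls against GFP were made for 6 genes, where independent lists would give 62.1. The comparisons share the GFP libraries, and in the simulations of unchanged groups 66.9% of genes on average had the same sign in both. A deficit of opposite calls is therefore partly built in. The lipid phosphate phosphatase gene wun2 rose by 1.02 with Ubx-WT (edgeR adjusted p = 0.00012), and with Ubx-N51A it changed by -1.32 (edgeR adjusted p = 0.00013). It kept both calls without each library in turn, and it was chosen for its direction, outside the naming rule.

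Fold changes were also set against gene structure, across genes, which are not independent replicates. Between Ubx-N51A and Ubx-WT the log2 fold change correlated with exon length at a Spearman rho of -0.374 over 9017 genes and -0.602 over the 6399 genes of at least 5 CPM. For Ubx-WT against GFP rho was 0.141 and 0.175, and for Ubx-N51A against GFP -0.15 and -0.263. Deviations of single libraries from the mean of all followed exon length too, with rho of -0.169, 0.127 and 0.16 for GFP, 0.216, 0.371 and 0.204 for Ubx-WT, and -0.473, -0.3 and -0.128 for Ubx-N51A. With the number of exons, rho between the Ubx proteins was -0.287 and -0.437.

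**Figure D5:**
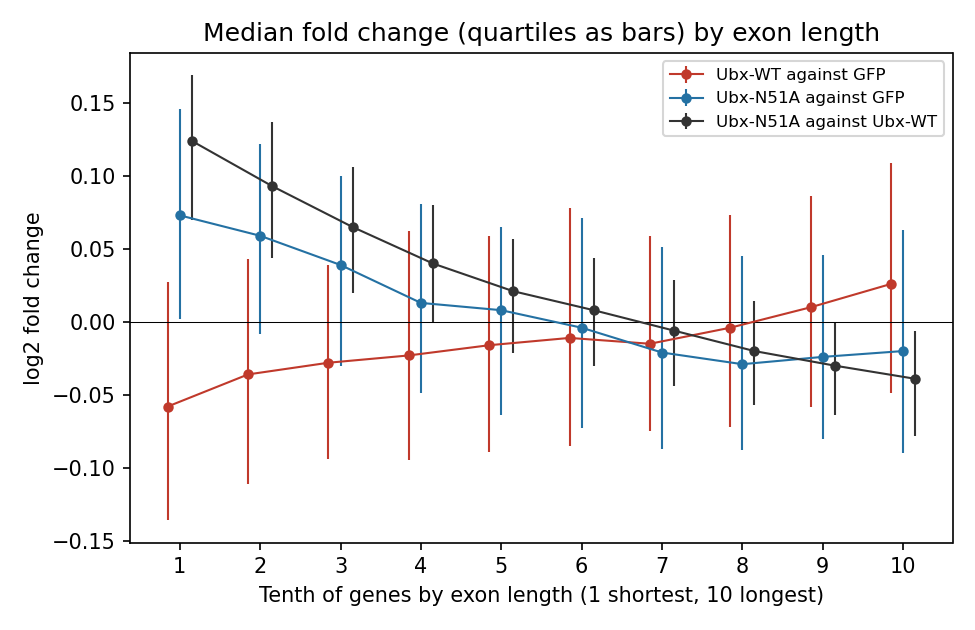
Median log2 fold change, with quartiles as bars, in 10 equal bins of the 6399 genes of at least 5 CPM ordered by exon length, for the 3 comparisons. Between Ubx-N51A and Ubx-WT the median runs from 0.12 in the bin of the shortest (median 720 bp) to -0.04 in the longest (7989 bp).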

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

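All tests on Hsp70Bb and w, the tests of chance shared through the controls, the fit corrected for exon length and the comparison of ribosomal protein genes with the spread between libraries were chosen only after the result was seen. Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, reached its own count of edgeR calls: 1524, 745 and 473 genes, with 0 as the highest of the other splits in each. At an unadjusted p under 0.05 those other splits reached at most 1334, 551 and 880 genes, and no other tool was run on them.

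The 6 genes called in opposite directions against GFP drew attention because the difference between the proteins was itself called by edgeR. All but Tig, a member of the integrin and basement membrane list, stand outside the naming rule. From Ubx-WT to Ubx-N51A the log2 change was -1.15 for Tig (adjusted p = 1.07e-05), -2.52 for the homeobox gene dve (0.000138), -2.24 for CG2444 (2.3e-05), -2.34 for wun2 (2.98e-07) and -1.49 for chas (7.16e-06). CG14866 had a fitted change of -8.35 (adjusted p = 1.4e-05), which is no bound: it had 138 reads with Ubx-WT, 8 with GFP and 0 with Ubx-N51A, at least 37.5-fold lower than with Ubx-WT and at least 2.6-fold lower than with GFP against a floor of 3 reads over the group. These differences kept their call without each library in turn, but of the calls against GFP only those of wun2 all did. The calls for Ubx-WT ended in 4 of 9 fits without 1 library for Tig (up to 0.12), in 2 for dve (0.0836) and in 3 for CG2444 (0.111). The calls for Ubx-N51A ended in all 9 for CG14866 (0.0474 with all libraries, up to 0.124 without 1) and in 5 for chas (0.133), so the opposite direction of CG14866 rests on a call that no such fit kept.

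Hsp70Bb and w were both lower with the Ubx proteins than with GFP: Hsp70Bb stood at 382 to 535 CPM with GFP, 93.1 to 126 with Ubx-WT and 138 to 148 with Ubx-N51A, and w at 194 to 243, 93.7 to 107 and 124 to 170. A weaker heat shock response stays open: the other 9 heat-inducible genes had a median log2 fold change of -0.04 with Ubx-WT and -0.158 with Ubx-N51A, above the bound of -0.4, but that set leaves out the Hsp70 copies, of which Hsp70Ab fell by 1.36 and 1.37, and its members went both ways, with Hsp83 lower by 0.24 and 0.26, Hsp68 higher by 0.26 with Ubx-WT (edgeR adjusted p = 0.0202, and 0.0959 without 1 library) and at 0.02 with Ubx-N51A, and DnaJ-1 at -0.08 and -0.07. Reads from an expression construct with Hsp70 and white sequence may contribute, since Hsp70Bb held at least 98.2% of the reads of the 6 Hsp70 copies in every library, although near-identical copies and unique mapping could also concentrate reads, and the construct's sequence is not given in the sources used here. One common change of such a construct predicted equal changes, and with Ubx-WT Hsp70Bb changed by -0.916 more than w (SE 0.16), past the 2 standard errors set as the bound. It was still left open, a decision made after the value was seen, because w also has reads of its own gene and would then move less. Between the Ubx proteins the group means did not follow that reason. From Ubx-WT to Ubx-N51A w rose more than Hsp70Bb by the ranges above (edgeR adjusted p = 0.00359 for w). Whether these 2 rises differ was not tested.

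For the 33 genes at least 2-fold lower with both proteins, among them upd1, upd2, upd3, Socs36E, CecA1 and PGRP-SC2, a single deviating GFP library is argued against: at least 90.9% of them stayed called in both comparisons without any 1 GFP library. Chance values shared through the GFP libraries stay open. The smaller of a gene's 2 falls had a median of 7.12 standard errors of the GFP mean, pooled over the set. It was at least 4.66 without 1 GFP library, above the 3.7 that allows for choosing among all tested genes. But the genes were chosen from the same data for called falls of at least 2-fold, which favours large falls and a small spread. With the pooled standard error of 0.204 even the lowest gene had 4.96, so passing the bound decides nothing. Without GFP replicates 1 and 2 the lowest gene had 3.5 and 3.13. This test replaced simulated calls, which were 0 and would be near 0 whatever the controls share, and the spread it uses is that of the 3 libraries kept by the submitters. The design has 1 kind of control, so an effect of GFP, or of the way those cells were made, cannot be told apart from an effect shared by the Ubx proteins. The latter, a response that does not need the residue changed in N51A, stays a hypothesis.

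Ribosomal protein genes were higher with Ubx-N51A than with Ubx-WT, by a median of 0.16, while short genes in general were higher too. Matched genes reached that median in 0.06% of 10000 draws, which met the bound of 5% set before the test and spoke against a trend with length and abundance as the whole cause. That bound was judged too easy to meet, because the draws treat genes as independent: the excess over matched genes was 0.034 with a jackknife standard error of 0.034 between libraries, a second criterion chosen after the first result, and it leaves the trend open. The fit corrected for exon length lowered the median to 0.075 and the called genes from 14 to 4, with a camera adjusted p of 1.37e-09, so part of the difference may come from a trend with length and the rest may be biological or technical. No single library decided it, since the lowest median without 1 library was 0.112, without Ubx-WT replicate 2.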

How the results depend on the processing

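The fits without mitochondrial-genome genes and corrected for exon length were chosen only after the data were seen. The counts of 1524, 745 and 473 called genes (Ubx-WT against GFP, Ubx-N51A against GFP, Ubx-N51A against Ubx-WT) stayed within 1.5 times with DESeq2 (1652, 951, 515), limma-voom (1569, 758, 462), the other scalings, no expression filter (1842, 953, 658), fits of 2 groups (1494, 715, 393), no mitochondrial genes (1580, 776, 485) and the length correction (1628, 796, 382, of which 1432, 668 and 362 were shared). Stricter thresholds left fewer by construction: 311, 94 and 208 genes with an absolute log2 fold change of at least 1 (66 in the overlap of 543), and 802, 287 and 250 at an adjusted p under 0.01. With genes of at least 5 CPM, where fewer genes were tested, the comparisons had 1071, 718 and 124 calls. Some genes above that level also lost their call between the Ubx proteins, such as SmF (66.0 to 97.2 CPM in these groups). Leaving genes out of the test is therefore not the whole cause of the fall to 124.

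Leaving out 1 library gave 990 to 1741 genes, 362 to 823 and 302 to 474, and an overlap of 281 to 544. Fewer samples enter these fits. The libraries that moved a count by over 1.5 times were GFP replicate 2 (1015) and Ubx-WT replicate 3 (990) in the first comparison, GFP replicates 1 (440), 2 (362) and 3 (490) and Ubx-N51A replicate 2 (398) in the second, and Ubx-WT replicate 3 (302) in the last. In the overlap they were GFP replicates 1 (329) and 2 (281) and Ubx-N51A replicate 2 (318). Abd-B between Ubx-N51A and GFP, with 2 reads against 1 and a log2 fold change of 0.83, ran from -1.96 without Ubx-N51A replicate 2 (edgeR adjusted p = 0.624), the library with its 2 reads, to 2.78 without GFP replicate 1.

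Whether the replicate numbers mark cultures made together was not settled. Deviations of libraries with the same title number correlated at -0.108 to 0.177, with 1 of 9 pairs over 0.1, against -0.251 to 0.236 for other pairs. These values show no clear pairing, but with 3 libraries per group they cannot exclude it. A replicate block by title number gave 1369, 607 and 401 genes, an overlap of 461 and 10, 10 and 9 called lists, without the heat shock list (camera adjusted p = 0.0506) and the ER stress list (0.0545) for Ubx-WT against GFP. The deposited files' names number the replicates differently from the titles. Deviations of libraries with the same file number correlated at -0.108 to 0.177, with 1 of 7 pairs over 0.1. A replicate block by those numbers gave 618, 178 and 294 genes, of which 61.5%, 42.7% and 15.6% were higher. GFP replicate 2 is the only library with its file number, so its block term took it out of the group comparisons. Other causes of the lower counts were not tested. Of the calls of named genes, 25 were not made with the former block and 81 with the latter.

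Of the 12, 9 and 9 lists called by camera, 0, 0 and 0 were called with an estimated correlation, which allows for members that vary together. The rotation test fry called 13, 10 and 5, and the cause was not tested for the last. For Ubx-WT against GFP fry lost the spliceosome (fry adjusted p = 0.107), mitochondrial ribosomal (0.0827) and oxidative phosphorylation (0.322) lists. For Ubx-N51A against GFP it lost the cell cycle list (0.351). Between the Ubx proteins it called 0 lists higher, where camera had called 5. Those were the ribosomal (0.0518), mitochondrial ribosomal (0.0648), oxidative phosphorylation (0.187), spliceosome (0.292) and cell cycle (0.385) lists. The length correction gave 11, 10 and 8, and it added the ribosomal proteins (camera adjusted p = 0.0479) and cell adhesion (0.0289) for Ubx-N51A against GFP, and the SR proteins and hnRNPs (0.0207) and the nucleolus (0.0341) between the Ubx proteins. Leaving out 1 library gave 10 to 12, 6 to 10 and 7 to 10. Named genes kept their direction in every setting but that of Abd-B, and lost their call in 6 cases with DESeq2, 2 with limma-voom, 14 with fits of 2 groups, 21 with genes of at least 5 CPM, 16 with the length correction and 314 of the fits without 1 library. No scaling moved the median of all genes by over 0.1. Depth limits the genes under 0.1 CPM, which had a few reads per library.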

Other observations

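Among genes near silence in the GFP cells, more were called higher with Ubx-WT than with Ubx-N51A. Of 70 tested genes with a mean under 0.1 CPM in GFP, edgeR called 65 higher with Ubx-WT and 6 higher with Ubx-N51A, and the 6 were among the 65. The direct test called 51 of the 65 lower with Ubx-N51A than with Ubx-WT. The expression filter admits such genes only where another group expresses them, so the share that rose is not a rate. The 65 were also chosen by their call with Ubx-WT, which favours a difference from Ubx-N51A. The 51 of 65 is therefore partly built in and is not a rate either. Summed reads with GFP, Ubx-WT and Ubx-N51A were 10, 291 and 11 for pwn, 5, 159 and 41 for Tmhs, 9, 131 and 30 for the opsin gene Rh5, 10, 124 and 14 for mspo, and 3, 106 and 10 for melt. Transcription factor genes in this set include ss (10, 68 and 12 reads) and vnd (9, 61 and 10 reads). These genes were chosen after their values were seen.

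Markers of cell types moved in few members and were not called by camera against GFP, while fry called 3 of these lists. With Ubx-WT, 3 of 16 neuron and glia markers rose, and 4 adjusted over the list alone (camera adjusted p = 0.229, fry adjusted p = 0.0105), 3 of 15 muscle markers rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.777), and 4 of 21 haemocyte markers fell, with 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.233). Of the 12 epithelium, cuticle and fat body markers 1 rose and 1 fell with Ubx-WT, also adjusted over the list alone (camera adjusted p = 0.256, fry adjusted p = 0.00202). With Ubx-N51A, 0 of 16 neuron and glia markers were called and 2 of 15 muscle markers fell, both also adjusted over the list alone, and 4 of 21 haemocyte markers fell and 1 rose, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.778, 0.373 and 0.0518, and fry adjusted p = 0.03 for the haemocyte markers). The muscle actin gene Act87E rose by 2.40 with Ubx-WT (edgeR adjusted p = 0.000804), and ItgaPS4, an integrin gene, fell by 0.52 with Ubx-WT and by 0.63 with Ubx-N51A. Act87E stayed low, with 11 reads over the GFP libraries and 71 over the Ubx-WT libraries. Signalling lists outside the JAK-STAT and stress-induced, JNK and Dpp lists were not called by camera in any comparison. With Ubx-WT 4 of 22 genes of the EGF and FGF pathways rose and 3 fell, with 4 and 4 adjusted over the list alone (camera adjusted p = 0.77). Of 19 Wingless genes 3 rose and 1 fell (camera adjusted p = 0.716, and fry adjusted p = 0.0331), of 16 Notch genes 1 rose and 1 fell (0.77), and of 21 Hedgehog and Hippo genes 1 rose (0.956), each also adjusted over the list alone. The Polycomb and trithorax list had 1 rise in 25 with Ubx-WT, and 0 adjusted over the list alone (camera adjusted p = 0.956), and 0 calls with Ubx-N51A, also adjusted over the list alone (0.615).

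The lists of lipid metabolism, detoxification, glycolysis and ecdysone response were not called by camera in any comparison. With Ubx-WT, 4 of 19 lipid and sterol genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.546), led by the fatty acid synthase gene FASN2 (1.64; edgeR adjusted p = 5.88e-05). With Ubx-N51A that list gave 1 rise and 2 falls, also adjusted over the list alone (camera adjusted p = 0.778), and FASN2 was lower than with Ubx-WT by 1.74. Of 23 detoxification genes 3 rose and 6 fell with Ubx-WT, with 4 and 7 adjusted over the list alone (camera adjusted p = 0.546), and 2 rose and 4 fell with Ubx-N51A, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.768). The glutathione S-transferase gene GstD3 fell by 0.89 and 0.52. Of 17 glycolysis genes 1 rose with Ubx-WT and 0 with Ubx-N51A, and of 18 ecdysone response genes 2 rose and 1 fell with Ubx-WT and 1 fell with Ubx-N51A, all also adjusted over the list alone (camera adjusted p = 0.47, 0.922, 0.77 and 0.836).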
